A study of Lytechinus variegatus with 8 samples.

How the data were processed

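Spine RNA of the sea urchin Lytechinus variegatus was sequenced from 4 wild-caught animals, with 1 library of primary spines and 1 of secondary spines per replicate number, 8 libraries in all. Per the series' design text, 50 primary or 100 secondary spines went into a library. Per the labels' protocols, RNA was extracted with TriZol and messenger RNA was selected with poly-T beads. The protocol text names a strand-marking and a non-marking version of the library without saying which was used, and the strand setting of the counting is not given in the sources used here. Reads of overlapping or antisense genes can therefore not be told apart. The submitters' processing notes name HISAT2 2.0.5 and featureCounts, and the design text names assembly 3.0 of this species as the reference. The treatment of reads that align to several places is not given in the sources used here, so values of genes that share a product name with others (tubulins, fibropellins, DMBT1-like, notch-like and mucin-like genes among those below) are uncertain. How similar their sequences are was not examined.

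The deposited counts are whole numbers of reads per gene, per the file headers, for 26814 genes. The deposited FPKM values cover the same 26814 genes. Each deposited FPKM value equalled the count divided by the gene length and by 1 library constant, to within 0.0001 reads. That constant was 0.905 to 0.994 times the total count in primary libraries and 1.062 to 1.082 times the total in secondary libraries, so the authors' FPKM carry a scaling between libraries in addition to depth. All 26814 gene IDs, starts and ends matched the reference gene table of assembly Lvar_3.0, and coordinates below are those of the deposited table, with chromosome numbers from the reference table. No read fell on 3028 genes. Product names are those of the deposited table, and its Swiss-Prot match is given for several named genes where it points to another protein.

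Groups came from the sample titles. The main test was the quasi-likelihood test of edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3 on the deposited counts, with group as the only term, TMM scaling and the filterByExpr filter, which kept 16788 genes. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called, two-sided. Log2 fold changes are secondary minus primary, so positive values are higher in secondary spines. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values are TMM-scaled, with SD over 4 libraries.

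The design text says that both kinds of spine came from the same 4 animals, and the titles number both kinds from 1 to 4. Deviations of log2 CPM from the group mean correlated at 0.733 to 0.811 between same-numbered libraries and at -0.317 to -0.200 between differently numbered ones, so a number was taken to mark an animal. A fit with the replicate number as a block was run as an alternative and is quoted where it changed a call or moved a count by over 1.5 times. The common biological coefficient of variation was 0.470 without the block and 0.183 with it. The main test leaves this pairing out, so genes that it did not call may still differ within animals. The balance of calls between the 2 directions also depended on the block. No library duplicated another of its group: counts of 2 libraries of the same group differed by a mean chi-square of 37.5 to 60.9 per gene. Primary libraries were not compared with secondary libraries in this way.

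Gene lists were fixed by name patterns before the data were examined. Of 28 lists, 27 could be formed. The list of transcription factors was not formed because the family column of the deposited table holds 706 general protein families for 10018 genes. After reading the gene names, and before any test, exclusions were added to 19 lists because patterns also caught unrelated names, which removed 781 entries. The original patterns were kept as an alternative. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and adjusted over the 27 lists. An estimated correlation, the rotation test fry, and an exact permutation test of the list mean over the 8 libraries were set beside it. Beside the members called over all genes, those called after adjustment over the list alone are given.

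Genes were named by a rule fixed before the data were examined. It took the 12 genes per direction with the largest absolute log2 fold change among calls with an informative name, a mean CPM of 5 or more and no overlap between the groups. It then took up to 4 called genes per list by smallest p, or up to 2 abundant members where a list had none, and the 5 most abundant genes of each group. Because the numbers pair the libraries, the first parts were repeated with the blocked calls, for up to 8 further genes per direction in each part.

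Alternatives were the replicate block, DESeq2 1.42.0 with and without the block, other scalings (RLE, library size alone), other filters, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a fold threshold, and leaving out each library or each animal. The exact permutation test of list means, a correction for gene length (a lowess of each library's deviation on log2 length, span 0.3, as an offset), the original list patterns, the block with an estimated correlation, and leaving out each animal from the blocked fit were added after the data were examined.

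The tests were checked on simulated counts made from the real gene means, library sizes and animal effects, with 200 changed genes. For this comparison, with 16206 genes tested, the fit without the block recovered 4 of 100 genes changed by log2 1 and 49 of 97 changed by log2 2, with 0 false calls among 53. The blocked fit recovered 64 of 100 and 96 of 97, with 21 false calls among 181 (11.6%, above the 5% aimed at). In a simulation on 16788 genes, camera called a list of 60 genes raised by log2 1, with the preset and with the estimated correlation, and 0 of 20 unchanged lists. Those lists were drawn at random, so they lacked the correlation of the real lists (estimated at 0.348 for cilia and 0.532 for ribosomal protein genes). The simulation could therefore not show false calls that such correlation brings. On 16788 simulated genes, the length correction lowered an imposed length trend from 0.300 to 0.010 log2 units per doubling of length. No genome sequence was used here, so GC content was not examined.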

Results

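Sea urchins carry long primary spines and shorter secondary spines, and the design asked which genes differ between them in Lytechinus variegatus. Messenger RNA was sequenced from 4 libraries of primary spines and 4 libraries of secondary spines, which came from 4 wild-caught animals of 1 color morph. Libraries held 9252184 to 10902546 counted reads. Primary libraries had reads on 19773 to 20170 genes and secondary libraries on 20652 to 21068 genes. Long noncoding RNA genes took 2.76 to 4.15% of the counts in primary and 3.75 to 5.68% in secondary libraries. The most abundant transcripts with a name came from soma ferritin-like LOC121421553, an iron storage protein, at 21480 ± 6944 CPM in primary and 12120 ± 1753 CPM in secondary spines (SD, n = 4). Cytoskeletal actin 1A LOC121428312 had 11810 ± 3754 and 7064 ± 1172 CPM. Neither gene passed the test (edgeR adjusted p = 0.0721 and 0.0964), and both were called lower in secondary spines with the replicate block (edgeR adjusted p = 0.0240 and 0.0186). The uncharacterized gene LOC121418514 had 13910 ± 8606 CPM in primary and 27950 ± 6708 CPM in secondary spines and did not pass (edgeR adjusted p = 0.247). Values after ± are SD over 4 libraries for CPM and standard errors for log2 fold changes. Adjusted p values of single genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

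Secondary spines had higher levels of cilia genes, of several transcription factors of patterning, and of single genes, among them tenascin-N-like, troponin T-like and Wnt-5b-like, that were close to undetected in primary spines. Primary spines had higher levels of an astacin-type protease, a fibropellin, a gene named cysteine-rich venom protein-like and a glutamate transporter. Of 16788 genes tested with edgeR, 1311 were called, 987 higher in secondary and 324 higher in primary spines. The median log2 fold change was 1.84 among the former and -0.84 among the latter. Of the 1311 calls, 1310 went the same way in all 4 animals. The groups did not overlap for 1302 of the calls, which by itself fixes that agreement, so it is no separate support. No informative name was given for 360 of the calls. The groups did not overlap for 2545 genes (15.2% of those tested, against 2.86% expected by chance for 8 independent libraries, which those of 1 animal are not). With the replicate block 4041 genes were called, 2077 higher in secondary and 1964 higher in primary spines, and these included 1309 of the 1311 calls. The share of calls higher in secondary spines was 75.3%, against 51.4% with the block and 87.9% (1225 and 168 genes) with scaling by library size alone, which moved the median log2 fold change of all genes from -0.026 to 0.139. It was 67.3% with the gene length correction and 44.5% (1941 and 2421 genes) with that correction and the block, where most calls were higher in primary spines. Log2 fold changes went with gene length (Spearman 0.182 across genes), with a median of -0.203 in the shortest 10% of genes and 0.096 in the longest 10%. The count higher in primary spines was 183 without primary library 1, and 186, 170, 204 and 158 without secondary libraries 1, 2, 3 and 4. The blocked count was 2379 without animal 1 and 2608 without animal 2.

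Tenascin-N-like LOC121430100 (chromosome 16, 8524694 to 8537826), which the deposited table matches to ficolin-2, had 2 reads in the primary libraries together and 1174 in the secondary libraries. The ratio of CPM was 539, with a 95% interval of 149 to 4450 that covers counting error only (log2 fold change 8.76 ± 0.88, edgeR adjusted p = 0.00127). Secondary library 1 had 61.0 CPM, the other secondary libraries 13.6 to 23.2 CPM, and the log2 fold change was 8.04 without library 1. The matrix metalloproteinase stromelysin-3-like LOC121431994 (chromosome 18, 6348802 to 6357041) had 0.135 ± 0.269 CPM in primary and 14.9 ± 5.29 CPM in secondary spines, a log2 fold change of 6.69 ± 0.96 (edgeR adjusted p = 0.00439). The deposited table matches it to the 50 kDa hatching enzyme. Its primary reads lay in library 1 alone, without which primary spines had 0 reads. The leucine-rich repeat gene LRRC15-like LOC121417626 (chromosome 6, 20273184 to 20356103) had 2.14 ± 0.483 and 94.2 ± 8.24 CPM, a log2 fold change of 5.45 ± 0.21 (edgeR adjusted p = 2.85e-05). CUB and sushi domain-containing 2-like LOC121430597, matched to plasminogen, rose by 6.16 ± 0.53, notch 2-like LOC121430595, matched to DMBT1, by 5.51 ± 0.57 and troponin T-like LOC121421391, of the muscle thin filament, by 5.63 ± 1.08 log2 units. Without 1 library the log2 fold change of the CUB and sushi gene reached 7.01 and that of the troponin gene went from 4.88 to 7.87. The DMBT1-like gene LOC121406844 rose by 5.68 ± 0.38, and 84 genes of the table share its product name. Genes of that name were also called lower in secondary spines. Among them were LOC121417615 (-2.41 ± 0.33, edgeR adjusted p = 0.0037) and LOC121406270 (-0.96 ± 0.17, edgeR adjusted p = 0.0094). SAMHD1-like LOC121407381, a nucleotide hydrolase, rose by 6.12 ± 1.20 (edgeR adjusted p = 0.0166). Its primary reads also lay in library 1 alone, and its call was lost without secondary library 4 (edgeR adjusted p = 0.0503).

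Among genes higher in primary spines, the astacin-type metalloprotease SpAN-like LOC121406098 (chromosome 19, 22952598 to 23003321) had 355 ± 67.6 CPM in primary and 15.5 ± 9.27 CPM in secondary spines, a log2 fold change of -4.51 ± 0.41 (edgeR adjusted p = 0.00106). Fibropellin-1-like LOC121428880 (chromosome 15, 25458378 to 25477580), of a family of apical matrix proteins, had 1735 ± 172 and 408 ± 99.9 CPM (log2 fold change -2.09 ± 0.19), and 45 genes share its product name. Cysteine-rich venom protein-like LOC121407478 (chromosome 2, 17833521 to 17853124), matched to peptidase inhibitor 16, had 589.7 ± 345 and 109 ± 38.1 CPM (log2 fold change -2.43 ± 0.42). Skin secretory protein xP2-like LOC121419659 had 123.4 ± 82.1 and 16.6 ± 4.85 CPM (log2 fold change -2.90 ± 0.53). The glutamate transporter EAAT1-like LOC121424431 had 555 ± 71.1 and 138 ± 33.2 CPM (log2 fold change -2.00 ± 0.19, edgeR adjusted p = 0.00111). The log2 fold change of the forkhead gene HNF3-beta-like LOC121419318, named by the repeat of the rule with blocked calls, was -1.81 ± 0.34 (edgeR adjusted p = 0.0127). The Wnt antagonist SFRP5-like LOC121416549 changed by -2.03 ± 0.42 log2 units (edgeR adjusted p = 0.0213), a call lost without primary library 1 or 3 or secondary library 1 or 2 (highest edgeR adjusted p = 0.0691). The uncharacterized gene LOC121422208, among the 5 most abundant of primary spines, had 9871 ± 2142 and 2575 ± 976 CPM (log2 fold change -1.94 ± 0.29, edgeR adjusted p = 0.00494).

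**Figure D1:**
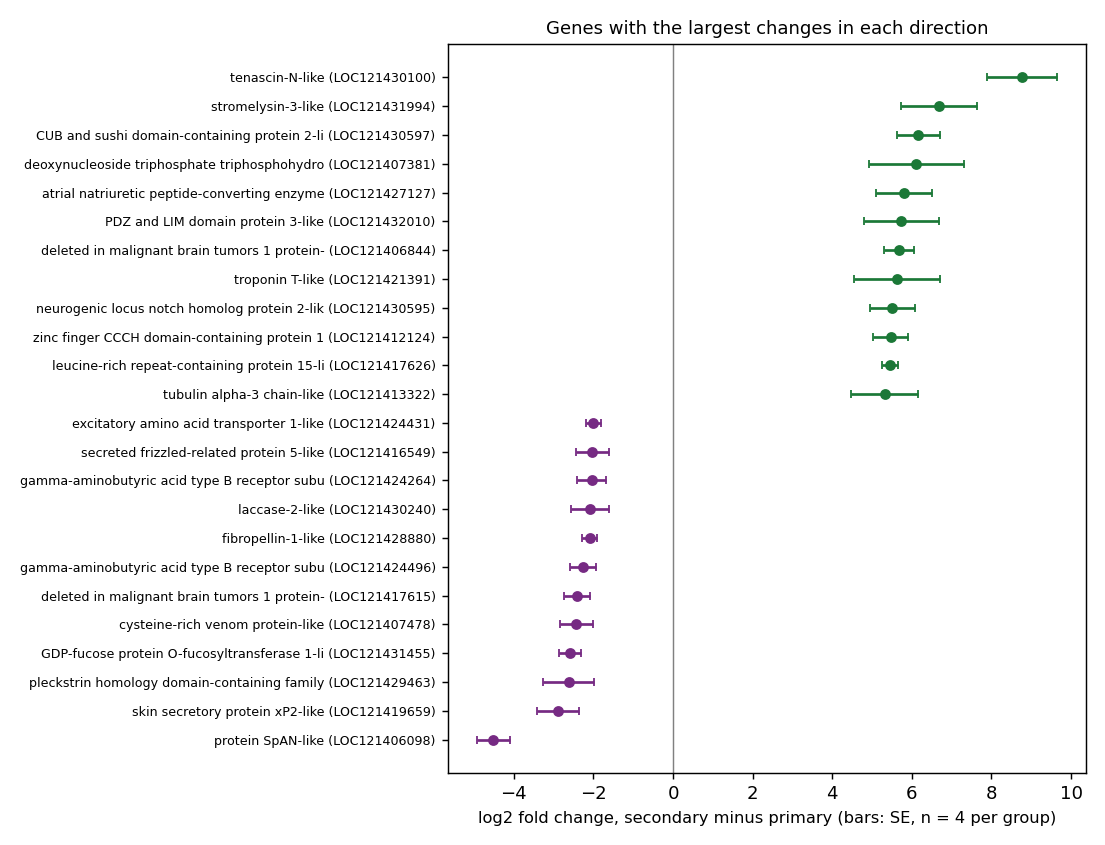
Log2 fold change (horizontal axis, secondary minus primary spines) of the 12 genes per direction with the largest changes among genes that met the naming rule. Points are edgeR estimates and bars are standard errors (n = 4 per group); SpAN-like stands lowest at -4.51, and all 12 genes higher in secondary spines lie above those higher in primary spines.

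Cilia genes, which encode the axoneme, its motors and its transport system, were higher in secondary spines. Of 151 tested members, 109 rose, 42 did not pass and 0 fell (130 and 0 adjusted over the list alone), with 0 lower at an unadjusted p below 0.05 in edgeR and 0 called lower by DESeq2. In the blocked fit adjusted over the list alone, 140 were higher and 1 lower, the dynein light chain LC6-like LOC121408814 (blocked log2 fold change -0.45 ± 0.18), which was named after its value was seen. The median log2 fold change was 1.63, with quartiles of 1.18 and 1.98. Axonemal dynein heavy chain 5-like LOC121408153 (chromosome 2, 45875119 to 45952880), a motor of ciliary beating, had 122 ± 24.7 CPM in primary and 478 ± 51.6 CPM in secondary spines (log2 fold change 1.98 ± 0.17, edgeR adjusted p = 0.000929). CFAP74-like LOC121428207 rose by 1.96 ± 0.17, CFAP46-like LOC121424906 by 1.88 ± 0.16 and SPAG16-like LOC121411288 by 2.17 ± 0.20 log2 units. The list was called by camera (adjusted p = 4.17e-60), with an adjusted p = 0.152 with an estimated correlation. The mean log2 CPM of the list was 3.96 ± 0.39 in primary and 5.53 ± 0.12 in secondary spines. A two-sided exact permutation test over the 8 libraries gave p = 0.0286, the smallest this design allows (0.0772 adjusted over 27 lists), and 10 of the 27 lists reached that p. The test does not take account of the pairing of libraries by animal. Within animals 1 to 4 the difference of the list mean was 1.27, 1.21, 1.58 and 2.22.

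**Figure D2:**
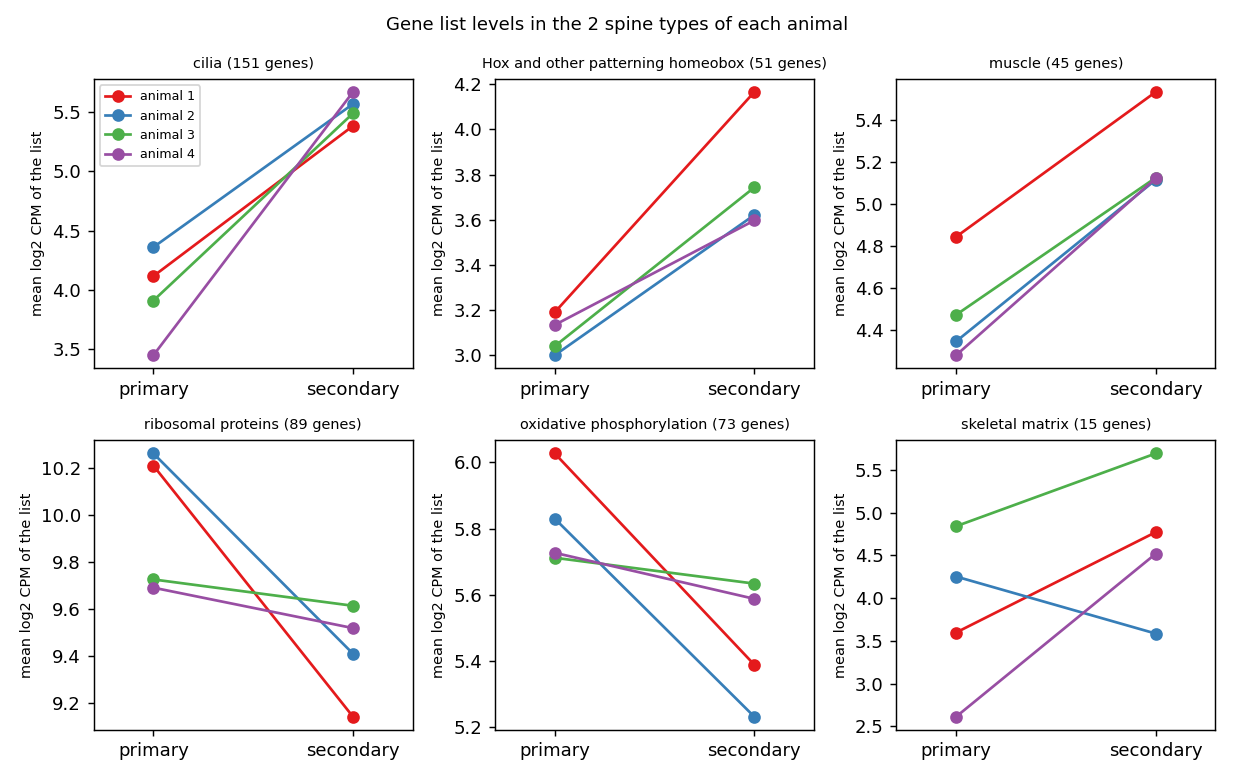
Mean log2 CPM (vertical axis) of 6 gene lists in the primary and secondary spines of each of the 4 animals; each line joins the libraries of 1 animal. The cilia lines differ by 1.21 to 2.22, while those of the skeletal matrix list range from -0.67 to 1.91.

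Homeobox and other patterning genes were higher in secondary spines for 10 of 51 tested members and lower for 0 (13 and 1 adjusted over the list alone, 16 and 2 with the block, 13 and 1 with DESeq2, 16 and 1 at an unadjusted p below 0.05). The median log2 fold change was 0.429. The members named here are not Hox cluster genes. The T-box factor Tbx2/3 LOC446194 (chromosome 2, 54787785 to 54823321) had 5.79 ± 1.20 CPM in primary and 36.3 ± 5.81 CPM in secondary spines (log2 fold change 2.64 ± 0.21, edgeR adjusted p = 0.000847). Pitx-like LOC121431895 rose by 3.93 ± 0.47, EMX1-like LOC121424701 by 2.56 ± 0.32 and the POU domain gene LOC121408306 by 1.59 ± 0.18 log2 units. The list was called by camera (adjusted p = 0.000409), with an adjusted p = 0.284 with an estimated correlation. Among signalling genes, Wnt-5b-like LOC121411849 had 0.262 ± 0.221 and 7.72 ± 2.89 CPM (log2 fold change 4.82 ± 0.70, edgeR adjusted p = 0.00465). BMP2-like LOC121432040, a secreted ligand, had 3 reads in the primary and 98 in the secondary libraries, a ratio of CPM of 30.0 with a 95% counting interval of 9.96 to 148 (log2 fold change 4.68 ± 0.86, and 5.63 without primary library 3, edgeR adjusted p = 0.0121). Growth/differentiation factor 8-like LOC121423561 changed by -1.73 ± 0.33 log2 units, a call lost without secondary library 4 (edgeR adjusted p = 0.0510). Notch 2-like LOC121422898 had 64.2 ± 8.75 and 276 ± 41.1 CPM (log2 fold change 2.10 ± 0.15), 9 genes share its product name, and it was matched to fibropellin-3. Of 44 Notch and Hedgehog genes, 4 were higher and 2 lower (6 and 3 adjusted over the list alone, 13 and 4 with the block). The 4 higher were LOC121422898, LOC121430595, LOC121431356 and LOC121426940, all notch-like by product name. The match was fibropellin-3 for LOC121422898 and DMBT1 for LOC121430595, and none was given for the others. Their part in Notch signalling is therefore uncertain. Of 20 Wnt genes, 1 was higher and 1 lower (1 and 5 adjusted over the list alone, 2 and 5 with the block). Of 26 TGF-beta and BMP genes, 1 was higher and 1 lower (1 and 1 adjusted over the list alone, 7 and 2 with the block). These signalling lists were not called by camera (adjusted p = 0.0530, 0.507 and 0.758), while fry called the Notch and Hedgehog list upward (fry adjusted p = 0.00826).

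Of 45 muscle genes, 5 were higher and 1 lower (8 and 1 adjusted over the list alone, 14 and 6 with the block). Their median log2 fold change was 0.085, and 0.003 with the gene length correction, while the mean was 0.635. The mean log2 CPM of the list differed by 0.692, 0.772, 0.655 and 0.845 within animals 1 to 4. Paramyosin-like LOC121426309, a thick filament protein, rose by 1.72 ± 0.29 and LOC121423244, named a titin homolog but matched to a protein other than titin, by 1.61 ± 0.11 log2 units, while another gene of that name, LOC121413265, changed by -0.65 ± 0.11. The list was called upward (camera adjusted p = 0.0324, and adjusted p = 0.297 with an estimated correlation). That call was lost without primary library 2 or 4 or secondary library 1 (camera adjusted p = 0.0707, 0.0522 and 0.0722) or without animal 2 (camera adjusted p = 0.0793), and with the gene length correction (camera adjusted p = 0.244). Secondary library 1 held the highest mean log2 CPM of the list, 5.54. Of 124 nervous system genes, with a median log2 fold change of 0.253, 8 were higher and 2 lower (9 and 4 adjusted over the list alone, 31 and 16 with the block). Without 1 library that median ranged from 0.154 (without secondary library 1) to 0.419 (without primary library 4). Synaptotagmin-1-like LOC121410540, a calcium sensor of synaptic vesicles, rose by 1.81 ± 0.24 log2 units, and the acetylcholine receptor subunit LOC121419139 changed by -1.08 ± 0.15. This list was called upward (camera adjusted p = 0.0386, and adjusted p = 0.457 with an estimated correlation), and the call was lost without primary library 2 or secondary library 1 (camera adjusted p = 0.0877 and 0.127) and without animal 1 or 2 (camera adjusted p = 0.0664 and 0.125). It was also lost with fry (fry adjusted p = 0.0696) and with the original name patterns (camera adjusted p = 0.0828), so it depended on names excluded before any test. Of 99 cell cycle genes, with a median log2 fold change of 0.239, 3 were higher and 0 lower (3 and 0 adjusted over the list alone, 10 and 1 with the block). They were centromere protein F-like LOC121425045 (1.49 ± 0.20, matched to RIMS-binding protein 2), the spindle pole gene CSPP1-like LOC121430966 (1.68 ± 0.15) and inner centromere protein A-like LOC121426383 (1.73 ± 0.37), whose call held in 1 of 8 fits that left out a library. The list call (camera adjusted p = 0.0288, and adjusted p = 0.504 with an estimated correlation) was lost without primary library 2 or secondary library 3 or 4 (camera adjusted p = 0.148, 0.0587 and 0.149), without animal 4 (camera adjusted p = 0.0794) and with fry (fry adjusted p = 0.135). Without 1 library the median of the list ranged from 0.116 (without secondary library 4) to 0.327 (without secondary library 2).

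Ribosomal protein genes were lower in secondary spines as a list, with a median log2 fold change of -0.58 and 1 of 89 members above 0. Of these, 0 were higher and 2 lower (0 and 59 adjusted over the list alone, 0 and 16 with the block). The called members were S21-like LOC121430841 (-0.67 ± 0.16, edgeR adjusted p = 0.0383) and L18-like LOC121422297 (-0.78 ± 0.20, edgeR adjusted p = 0.0472), and their calls held in 3 and 1 of 8 fits that left out a library. Both calls ended with the gene length correction (-0.49 ± 0.13, edgeR adjusted p = 0.0530 and -0.61 ± 0.17, edgeR adjusted p = 0.0600), which brought the fold changes nearer to 0; the median length of the list was 724 bases, against 2781.5 for all tested genes. The list was called by camera (adjusted p = 1.23e-18, and adjusted p = 0.325 with an estimated correlation) and not by fry (fry adjusted p = 0.0644). Its mean differed by -1.07, -0.85, -0.11 and -0.17 log2 units within animals 1 to 4. Oxidative phosphorylation genes had a median of -0.37 (camera adjusted p = 4.64e-10, and adjusted p = 0.325 with an estimated correlation) and were not called by fry (fry adjusted p = 0.0644). Their mean differed by -0.64, -0.60, -0.08 and -0.14 log2 units within animals 1 to 4. Of 73 members, 0 were higher and 1 lower (0 and 0 adjusted over the list alone, 0 and 18 with the block), with 17 lower at an unadjusted p below 0.05 and 6 called lower by DESeq2. The called gene was the complex I subunit NDUFB7-like LOC121423869 (-0.57 ± 0.13, edgeR adjusted p = 0.0275), whose call held in 2 of 8 fits that left out a library. Of 55 digestive enzyme and yolk genes, 0 were higher and 1 lower (0 and 1 adjusted over the list alone, 2 and 20 with the block), and the called member was the lysosomal sulfatase arylsulfatase A-like LOC121408846 (-1.41 ± 0.17, edgeR adjusted p = 0.00224). Of 54 autophagy and lysosomal protease genes, 1 was higher and 2 lower (1 and 2 adjusted over the list alone, 1 and 14 with the block), among them cathepsin B-like LOC121416026 (-0.74 ± 0.15), a call lost without secondary library 1, 2 or 4 (highest edgeR adjusted p = 0.0638), and LAPTM4A-like LOC121430636 (-0.76 ± 0.14). Both lists, with medians of -0.402 and -0.224, were called downward (camera adjusted p = 0.00194 for each), with an adjusted p = 0.152 and 0.284 with an estimated correlation.

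The 15 tested skeletal matrix genes, which encode proteins of the calcified skeleton, had a median log2 fold change of 0.63. Of these, 1 was higher and 0 lower (1 and 0 adjusted over the list alone, 1 and 0 with the block). The called gene was perlucin-like LOC121424079, matched to pulmonary surfactant-associated protein A. It had 4.44 ± 2.23 and 13.7 ± 3.04 CPM (1.63 ± 0.36, edgeR adjusted p = 0.0274), and its call held in 1 of 8 fits that left out a library. The list was not called (camera adjusted p = 0.0667), and was called upward with the block (camera adjusted p = 0.0367, and adjusted p = 0.653 with the block and an estimated correlation). Its mean differed by 1.17, -0.67, 0.85 and 1.91 log2 units within animals 1 to 4. Of 48 genes of ion transport for calcification, 0 were higher and 0 lower (0 and 0 adjusted over the list alone, 2 and 4 with the block), with 3 higher and 4 lower at an unadjusted p below 0.05, and 1 and 1 called by DESeq2. The proton pump subunit LOC121414246 had 700.2 ± 162 and 559.6 ± 132.9 CPM, and the calcium pump LOC121411017 had 688 ± 72.9 and 537 ± 72.3 CPM (log2 fold change -0.36 ± 0.13, edgeR adjusted p = 0.164, and -0.51 ± 0.11, edgeR adjusted p = 0.0268 with the gene length correction). Of 19 skeletogenic regulators, 2 were higher and 0 lower (2 and 1 adjusted over the list alone, 2 and 3 with the block). They were the cell adhesion genes kin of IRRE-like 2 LOC121413957 (2.33 ± 0.40) and kin of IRRE-like 1 LOC121420391 (1.32 ± 0.29), the latter called in 3 of 8 fits that left out a library. Of 28 collagens, 0 were higher and 1 lower (0 and 1 adjusted over the list alone, 2 and 5 with the block), and the called gene was alpha-1(X)-like LOC121427569 (-1.31 ± 0.29, matched to a complement C1q-like protein), called in 2 of those 8 fits. None of these lists was called by camera without the block (adjusted p = 0.262, 0.383 and 0.415).

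The remaining lists were not called by camera (adjusted p = 0.0530 to 0.801), and several had members called in both directions. Of 110 other matrix genes, 8 were higher and 8 lower (14 and 15 adjusted over the list alone, 21 and 34 with the block), and laminin beta-1-like LOC121416226 (matched to laminin alpha-2) and fibrillin-2-like LOC121431380 rose by 1.74 ± 0.17 and 2.09 ± 0.23 log2 units. Of 42 matrix proteases and inhibitors, 2 were higher and 4 lower (2 and 4 adjusted over the list alone, 3 and 9 with the block). Of 75 actin and tubulin genes, 13 were higher and 5 lower (16 and 13 adjusted over the list alone, 19 and 26 with the block). Tubulin beta-like LOC121428185 had 648 ± 88.4 and 179 ± 36.6 CPM (-1.86 ± 0.18), and tubulin beta-4B-like LOC121427504 had 12.7 ± 5.11 and 88.9 ± 25.7 CPM (2.80 ± 0.33), and 11 and 3 genes of the table have their product names. Of 63 mucus genes, 4 were higher and 0 lower (4 and 0 adjusted over the list alone, 11 and 9 with the block). Among those 4, mucin-2-like LOC121424405 had the smallest edgeR p (1.79 ± 0.18). The largest log2 fold change was that of integumentary mucin A.1-like LOC121409342 (1.91 ± 0.43), called in 1 of 8 fits that left out a library. Of 37 epithelial adhesion genes, 3 were higher and 2 lower (3 and 3 adjusted over the list alone, 5 and 6 with the block), and integrin alpha-V-like LOC121426066 changed by -0.83 ± 0.09. Of 172 immune and coelomocyte genes, 3 were higher and 6 lower (1 and 2 adjusted over the list alone, 16 and 35 with the block). Of 38 pigment cell genes, 0 were higher and 2 lower (0 and 1 adjusted over the list alone, 0 and 6 with the block). Of 102 stress genes, 0 were higher and 2 lower (0 and 0 adjusted over the list alone, 4 and 18 with the block). Of 20 phototransduction genes, 2 were higher and 0 lower (3 and 0 adjusted over the list alone, 2 and 1 with the block). Of 19 venom genes, 2 were higher and 2 lower (2 and 3 adjusted over the list alone, 2 and 5 with the block), and fry called this list downward (fry adjusted p = 0.0122). Of 13 germ line genes, 0 were higher and 0 lower (0 and 0 adjusted over the list alone, 1 and 0 with the block), with 1 higher and 0 lower at an unadjusted p below 0.05 and 1 and 0 called by DESeq2. Piwi-like LOC121408762 had 160.5 ± 5.57 and 161 ± 11.3 CPM, and speract receptor-like LOC121422745, of a family of sperm receptors for an egg peptide, had 78.5 ± 16.4 and 117 ± 9.57 CPM (log2 fold change 0.57 ± 0.16, edgeR adjusted p = 0.0741, and 0.00870 with the block), higher in secondary spines in 4 of 4 animals. Median and mean log2 fold change had opposite signs for other matrix genes (-0.19 and 0.18), actin and tubulin genes (-0.20 and 0.45) and TGF-beta and BMP genes (-0.05 and 0.19). The camera direction was down for the Wnt list, whose median was 0.07. With scaling by library size alone, the medians of the collagen, stress, ion transport, venom, epithelial adhesion and TGF-beta lists turned from negative to positive.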

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

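No test in this part was chosen after its result was seen. Each value below lay farther from the other 3 values of its group of 4 than Dixon's test for a single distant value allows at the 95% level. Of 349 groups of 4 values examined, 35 held such a value, against about 17.4 for independent, normally distributed values. The groups share libraries, so they are not independent, and CPM values of genes with few reads are not normally distributed. A group with reads in a single library always holds such a value. The number 17.4 is therefore not the chance expectation here, and no conclusion is drawn from the comparison.

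Myosin light chain kinase-like LOC121424934 had 8.39 CPM in primary library 1 and 273 CPM in secondary library 1, against 0 in the other primary libraries and 53.5 to 78.6 CPM in the other secondary libraries. Cysteine and glycine-rich protein 1-like LOC121421073 had 2.37 and 46.4 CPM in the same libraries, and PDLIM3-like LOC121432010 had 0.645 and 18.4 CPM. Troponin T-like LOC121421391 had 1.29 CPM and twitchin-like LOC121418826 had 22.1 CPM in primary library 1, and calmodulin LOC121418502 had 151 CPM in secondary library 1. The mean log2 CPM of the muscle list was 5.54 in secondary library 1, where that of the nervous system list was 3.86.

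Other values of animal 1 were a mitochondrial share of 1.18% of the counts in primary library 1, and in that library stromelysin-3-like LOC121431994 at 0.538 CPM, SAMHD1-like LOC121407381 at 3.01 CPM and piwi-like LOC121408762 at 152 CPM. In secondary library 1, SpAN-like LOC121406098 had 29.3 CPM, integrin alpha-V-like LOC121426066 109 CPM, a titin homolog, LOC121408908, 73.4 CPM, GABA receptor alpha-5-like LOC121414920 10.4 CPM and protocadherin Fat 4-like LOC121412741 116 CPM.

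In animal 2, CFAP74-like LOC121428207 had 21.1 CPM and laminin beta-1-like LOC121416226 had 27.7 CPM in the primary library. In its secondary library the mitochondrial share was 0.640%, uronyl 2-sulfotransferase-like LOC121428172 had 26.8 CPM and chondroadherin-like LOC121410017 had 10.98 CPM. In animal 3, the primary library had 2.11 CPM of CUB and sushi domain-containing 2-like LOC121430597, 28.2 CPM of the titin homolog LOC121408908 and 62.8 CPM of matrix metalloproteinase-16-like LOC121427699, and the secondary library had 15 CPM of hyalin-like LOC121431108. In animal 4, the primary library had 24.7 CPM of retinal guanylyl cyclase 1-like LOC121428357 and 18.2 CPM of chondroadherin-like LOC121410017. Its secondary library had 75.4 CPM of SAMHD1-like LOC121407381, 289 CPM of integrin beta-1-A-like LOC121426622 and a mean log2 CPM of 4.38 for the other matrix list, and its within-animal median difference of the cell cycle list was 0.363.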

How the results depend on the processing

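Tests with a length correction, with the original list patterns, with the block and an estimated correlation, and without each animal in the blocked fit were chosen only after the data were seen. Every gene called both in the main fit and in an alternative had the same direction in both. For calls lost in an alternative, the direction was compared for named genes alone. None of the called named genes reversed with the block, with DESeq2, with the length correction or without 1 library. Against 1311 calls (987 higher in secondary and 324 in primary spines), the replicate block gave 4041 (2077 and 1964), DESeq2 2154 (1436 and 718, with no adjusted p for 4576 genes), DESeq2 with the block 4043 (2097 and 1946), and the length correction with the block 4362 (1941 and 2421); the fits with a block had a smaller spread (coefficient of variation 0.183 against 0.470). Scaling by library size alone left 168 higher in primary spines and a log2 fold change of 1 or more left 131. RLE, the filters, limma on log2(FPKM + 1) or log2(FPKM + 0.1) and the length correction alone gave 1149 to 1430 calls. Without 1 library the calls ranged from 876 to 1125 (718 to 877 higher in secondary, 158 to 254 in primary), and without 1 animal from 626 to 804 (529 to 677 and 94 to 127), with fewer samples. The blocked count ranged from 2379 to 3221 without 1 animal. Of 27 lists 9 were called by camera, 10 with the block, 9 with the original list patterns, 8 with the length correction, 7 by fry (without the ribosomal, oxidative phosphorylation, nervous system and cell cycle lists, and with the Notch and Hedgehog and the venom lists) and 6 to 13 without 1 library or animal. With an estimated correlation 0 were called, 3 at an unadjusted p below 0.05, and with the block and an estimated correlation 0, 1 at an unadjusted p below 0.05. Of 129 named genes 105 were called, 77 of them in all fits without 1 library and 28 not; the block called 18 more and lost 0, DESeq2 called 13 more, and the length correction kept 99 of the 105, lost 6 and called 2 more. In simulated data 11.6% of the blocked calls were false, so the blocked counts may hold more false calls than the 5% aimed at. That simulation changed 200 genes, with 16206 tested, while the real blocked fit called 4041 of 16788. The share of 11.6% therefore need not hold for the real counts. Apart from the calls it added, named above or counted here, the block changed no call of a list or named gene. The causes of the other differences were not tested. Depth limits genes with few reads: a count of 3 over a group was 0.0786 CPM in primary and 0.0721 CPM in secondary spines.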

Other observations

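The tests of length, scaling and germ line RNA for the cilia list, those of length and scaling for the ribosomal list, the spread asked of the animal test and the restriction of neighbours to informative names were chosen only after the results were seen. Higher in secondary spines were GABA receptor alpha-5-like LOC121414920 (0.267 ± 0.332 and 6.60 ± 2.54 CPM, log2 fold change 4.58 ± 0.83) and the kainate receptor 2-like LOC121413970 (1.42 ± 0.922 and 6.74 ± 2.30 CPM, log2 fold change 2.24 ± 0.50), the latter called in 2 of 8 fits that left out a library. Lower were the GABA type B receptor genes LOC121424496 (-2.26 ± 0.34) and LOC121424264 (-2.04 ± 0.37), the serotonin receptor 1F-like LOC121426205 (-1.99 ± 0.30) and the muscarinic acetylcholine receptor LOC121414221 (-0.76 ± 0.14). A pair of onecut 2-like transcription factor genes on chromosome 6, LOC121416944 and LOC121416890, had 1.47 ± 0.752 and 40.4 ± 11.8 CPM and 1.83 ± 1.14 and 43.7 ± 7.37 CPM, log2 fold changes of 4.77 ± 0.42 and 4.56 ± 0.44. A pair of multicopper oxidase genes close together on chromosome 16, laccase-2-like LOC121430240 and L-ascorbate oxidase-like LOC121430027, changed by -2.08 ± 0.47 and -1.86 ± 0.45, calls that held in 3 and 1 of 8 fits that left out a library, and the latter ended with the gene length correction (-1.73 ± 0.46, edgeR adjusted p = 0.0557). Without primary library 4 the log2 fold change of GABA receptor alpha-5-like was 5.81.

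Within the cilia list, the hypothesis that axoneme genes rose more than genes of intraflagellar transport and the Bardet-Biedl complex was tested. The median log2 fold change was 1.76 for 110 axoneme members, of which 85 were called higher, and 1.07 for 29 transport members, of which 14 were called higher. The difference of medians was 0.686, with a permutation p of 3e-05 across genes, which are not independent replicates. A few single cilia genes had been seen before the test was written.

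The cilia list was higher in secondary spines, with a median log2 fold change of 1.63, a camera call lost with an estimated correlation (adjusted p = 0.152, and 0.630 with the block). A trend with gene length as the whole cause is argued against by a median of 1.637 after the length correction with the block. The lowest median of the list over RLE, library size alone and the deposited FPKM was 1.627. The median of all genes was -0.03 to 0.139 under these scalings. A difference of this size could therefore not have vanished under them, and no conclusion on scaling is drawn. RNA from gonad or sperm cannot be told apart: the germ line median was 0.005, but the 13 members had a median of 27.6 CPM in primary spines already, which would hide a small share, and speract receptor-like LOC121422745 was higher with the block. A larger share of ciliated cells in secondary spines, regulation within those cells and the pooling of 100 secondary but 50 primary spines could each account for the pattern, and were not tested. The number of spines pooled cannot be separated from the spine type in this design.

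The ribosomal protein list was lower in secondary spines, with a median log2 fold change of -0.58 and 2 of 89 members called, a camera call lost with an estimated correlation (adjusted p = 0.325) and with fry (fry adjusted p = 0.0644). Its median was -0.398 after the length correction with the block (-0.552 with the block alone). This argues against length as the whole cause, although the correction made the difference smaller. Under the other scalings its median was -0.404 at the highest. The median of all genes was at most 0.139 under these, so a difference of this size could not have vanished under them. Whether some animals alone carried the pattern cannot be told apart: the within-animal medians were -1.06, -0.85, -0.11 and -0.18, and the highest, -0.111, barely passed the bound of -0.1 set for it. A biological difference between the spine types stays open and was not tested.

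Genes called in the same direction lay next to each other on the chromosomes in 124 adjacent pairs, against a mean of 64.2 and a highest value of 95 over 10000 random placements, which argues against chance placement. Without pairs of the same product name there were 116 such pairs, against a highest random value of 92. Among pairs with informative names on both sides there were 49, against a random mean of 36.6 and a highest value of 63, so shared reads or split copies of 1 gene cannot be told apart from neighbours that change together. The GABA type B receptor genes LOC121424264 and LOC121424496, which end at 22522012 and start at 22522119 on chromosome 11, may be such a case. A run of 4 genes on chromosome 7 held dynein-2 light intermediate chain-like LOC121419117 (1.13 ± 0.21), LOC121419121 (1.18 ± 0.20), LRRC9-like LOC121419120 (2.03 ± 0.26) and CDKL1 LOC121419122 (0.59 ± 0.11), all higher in secondary spines in 4 of 4 animals. Another run of 4, on chromosome 9, held the soluble guanylate cyclase genes LOC121421582 (0.99 ± 0.14) and LOC121421586 (0.99 ± 0.16). It also held the uncharacterized genes LOC121421316 (2.28 ± 0.45) and LOC121422157 (6.85 ± 0.96), and all 4 were higher in secondary spines in 4 of 4 animals.

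Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, reached the count of 1311 calls (highest other 125), the 987 in the more frequent direction (75) or the 324 in the other (50). These splits treat the libraries as independent, which those of 1 animal are not. The 125 calls came from 1 of the 3 splits that kept both libraries of every animal together and so compared animals with animals. Among the 8 splits that part all 4 animals, too few for a share under 0.05, the real one called 1311 genes and the highest other 0, and with the block 4041 and 0. For the 9 lists called by camera, chance cannot be excluded, since 5 of 35 splits, and 4 of the 8 that part all 4 animals, called as many (the real one included), up to 14.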
